A study of Arabidopsis thaliana with 28 samples.

How the data were processed

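RNA from whole Arabidopsis thaliana seedlings was sequenced in 28 libraries that fall into 10 groups of genotype and condition. The genotypes are the wild type Col-0 and 3 mutants, lsm8, pfd4 and pfd246. LSM8 is a subunit of the nuclear LSM ring that binds U6 small nuclear RNA, and PFD2, PFD4 and PFD6 are subunits of prefoldin, a chaperone that passes proteins such as tubulin to the chaperonin CCT. Per the labels, standard seedlings grew in soil for 14 days at 20 °C, cold seedlings spent their last day at 4 °C, and salt seedlings grew in vitro with 150 mM NaCl. Salt is therefore tied to the growth medium, and each salt library is compared only with salt libraries of Col, or through the difference between genotypes. Col and lsm8 have 3 libraries in each condition, pfd246 has 3 in standard conditions, and pfd4 has 3 in cold, 2 in standard conditions (B and C) and 2 in salt (A and C). The labels name RNeasy plant mini kits for the RNA and a TruSeq stranded mRNA kit for the libraries, and call the replicates biological samples with no further detail, so that the p-values measure the spread between these samples.

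The deposited count tables hold raw counts, per the file headers and the values: reads per gene, reads per intron, reads across the border at each end of an intron, and reads spliced at each junction, with 1 set of tables for each comparison of a mutant with Col. The authors also deposited test tables whose columns hold a log2 fold change and a p-value per gene or intron, which serve here only for a count of calls. The other kind of content used, per the file headers, is text that gives the type of each exon part and the names of its inclusion and exclusion junctions [other]. The submitters' processing notes name TopHat2 and TAIR10, and the role and version of each are not given in the sources used here. No reference genome was used, so splice site sequences were not analysed. Symbols come from a RefSeq name table for TAIR10.1, which matched 32835 of the 33602 genes and gave a symbol for 10654. All coordinates printed are those of the deposited tables.

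The 12 library columns that stand in more than 1 gene table were identical between tables. The border counts were not: for 7857 introns the counts at the first border differ between tables for the same library, with a window of 131 bases in the standard and cold tables of lsm8 and pfd4 and of 135 in the others, while the second border has 135 in all and 0 differences. Tests over equal first windows therefore use both borders, and the others the second border alone. The salt libraries also differ in their junctions: 8760 of the 116196 annotated junctions seen occur only in the 8 salt libraries, 69 of them with over 1000 reads, against 713 only in the other 20 libraries. The shortest junction spans 10 bases in the salt libraries and 50 elsewhere (51 in 1 library). Differences that involve salt and another condition thus carry the alignment as well as the medium.

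Reads assigned to genes numbered 32.0 to 70.0 M per library (mean 51.7, SD 9.88, n = 28), and spliced junction reads 8.69 to 19.2 M. The lowest group mean was that of pfd4 in cold (36.8 M reads, SD 7.33, n = 3) and the highest that of Col in cold (59.6 M reads, SD 8.95, n = 3). Precision at this depth was tested on simulated counts with 200 changes each, not real libraries. For lsm8 in standard conditions the gene test found 91.0% of 1.5-fold, 98.5% of 2-fold and 100% of 4-fold changes, with 9 genes called that had been left unchanged, among 20578 tested. With the 2 pfd4 standard libraries it found 79.1%, 98.5% and 100%, with 7 unchanged genes called among 21023 tested. The intron test found 2.99%, 29.9% and 72.7% of 2-fold, 4-fold and 8-fold changes in odds in lsm8 and 4.48%, 37.3% and 74.2% in pfd4, the exon part test 4.48%, 52.2% and 74.2% in lsm8 and 5.97%, 34.3% and 75.8% in pfd4, and the gene interaction of lsm8 and cold 61.2%, 86.6% and 100% at 1.5-fold, 2-fold and 4-fold.

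Genes were tested with edgeR quasi-likelihood fits (edgeR 4.0.16, limma 3.58.1, R 4.3.3) after TMM scaling, the default filter on low counts and robust dispersions, each pair of groups fitted alone, with 2-sided p-values adjusted by Benjamini-Hochberg (BH) and a threshold of 0.05. CPM values are counts per M reads in genes (M for mega) without TMM factors, as mean and SD over libraries. The median gene moved by 0.27 (log2) between CPM ratios and TMM fold changes in pfd246 in standard conditions, by 0.25 in pfd246 against pfd4, by 0.13 in lsm8 in salt, by -0.11 in pfd4 in cold and by -0.14 in the pfd4 and cold interaction. Fold changes are relative to the TMM scale. With RLE factors or DESeq2 the median gene moved by under 0.1. Of 128782 introns, 5547 that hold another feature were left out, and 109954 had a spliced read and belonged to 1 gene. Retention was tested as the odds of border reads against spliced reads in an edgeR quasi-likelihood model with a term for each library, over introns with a mean coverage of at least 10 reads per library in each group and at least 5 border reads. Percent retention is the mean border count over that mean plus the spliced count. Exon parts (1901 annotated skipped exons and alternative splice sites with both kinds of junction seen) were tested with inclusion against exclusion junction reads in the same way. Differences between effects in separate conditions were tested as interaction terms. Pooled retention over 58995 introns and the percent of junction reads on unannotated junctions were compared with 2-sided exact permutation tests, which with 3 libraries against 3 cannot give a p below 0.1.

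Gene lists were tested with camera in limma with a preset correlation of 0.01 and, as an alternative, an estimated one. The 16 lists hold 222 genes: the mutated genes, LSM and prefoldin subunits, cold-regulated genes, ABA and salt genes, the circadian clock, flowering time, photosynthesis, tubulin and actin, the chaperonin CCT, heat shock proteins, splicing factors, salicylate defence, jasmonate, flavonoid synthesis, root markers and seed markers. These lists, the tests, the rule for naming genes (the mutated genes, up to 6 of the largest changes in each direction above 5 CPM, and up to 2 list members in each direction) and the first set of alternatives were chosen before the data were examined. That set comprises DESeq2 1.42.0, RLE factors, no filter on low counts, a term for the replicate letter, each library left out, all 28 libraries in 1 fit, coverage minima of 30 and 1, limma on log2 odds of introns with 0.5 added, retention at coverage 30, junctions with at least 5 reads, and overlaps by the other tools' calls. Chosen after seeing the data were the second border alone, both borders for joined tables, pooled retention at the second border, a length trend removed (spline with 5 degrees of freedom), unannotated junctions without those that join 2 genes, the library labelled lsm8 cold replicate C left out of lists and overlaps, limma for exon parts, and Col cold libraries thinned to the pfd4 depth. Overlaps of calls that share the Col libraries were set against independent lists and simulated mutants that share Col libraries (20 simulations for genes, 4 for introns). Independent changes, chosen after seeing the data, are the called ones, those of the second mutant dealt at random within deciles of Col level (10 and 4 simulations). Tables were prepared with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and plots with matplotlib 3.10.9. The exon and intron test tables, read densities and joined event tables of the authors were not analysed here beyond the counts of calls.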

Results

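The series asks which splicing events change in prefoldin and lsm8 mutants under different environments, and the mutated genes come first. LSM8 (chromosome 1, 24434203 to 24436294) stood at 7.77, 10.6 and 9.97 CPM in the 3 Col standard libraries and at 1.18, 1.62 and 1.19 CPM in lsm8 (log2 -2.86, SE 0.16, edgeR adjusted p = 1.23e-09). In salt it stood at 10.5, 12 and 14.0 CPM in Col and at 2.34, 1.80 and 1.76 CPM in lsm8 (log2 -2.76, SE 0.15, edgeR adjusted p = 3.32e-06). In cold it stood at 29.9, 30.1 and 32.9 CPM in Col. In lsm8 in cold it stood at 3.79 and 3.92 CPM in A and B but at 15.8 CPM in the library labelled lsm8 cold replicate C. The difference in cold did not pass the test (log2 -1.86, SE 0.65, edgeR adjusted p = 0.0873). PFD4 (chromosome 1, 2809778 to 2811191) was lower in pfd4 in standard conditions (3.11 and 3.60 CPM against 13.0, 11.1 and 11.9 in Col, log2 -1.86, SE 0.13, edgeR adjusted p = 8.43e-06). It was lower in cold as well (3.0, 3.01 and 4.31 against 24.7, 23.9 and 23.7, log2 -2.71, SE 0.12, edgeR adjusted p = 4.4e-09). In salt PFD4 stood at 6.54 and 6.32 CPM in pfd4 and at 14.1, 14.2 and 17.7 in Col (edgeR adjusted p = 0.00899, and 0.0558 without Col salt B). The library labelled lsm8 cold replicate C also held less PFD4 (10.7 CPM) than lsm8 cold A and B (21 and 20.9).

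In pfd246, PFD2 (chromosome 3, 7968078 to 7969705) stood at 3.13, 3.91 and 3.83 CPM against 20.2, 21.6 and 22.4 in Col (log2 -2.83, SE 0.10, edgeR adjusted p = 1.24e-12). PFD4 stood at 3.71, 4.36 and 4.23 CPM (log2 -1.82, SE 0.11, edgeR adjusted p = 7.77e-10). PFD6 (chromosome 1, 10507593 to 10509098) was not detectably lower: 28.3, 28.8 and 28.9 CPM in pfd246 and 22.9, 21.6 and 20.8 in Col (log2 0.13, SE 0.07, edgeR adjusted p = 0.125). LSM8 rose in pfd246 (16.8, 15.1 and 15.4 CPM, edgeR adjusted p = 0.00184, and 0.262 with all 28 libraries in 1 fit). As a list the 4 mutated genes had 1 member lower in lsm8 in standard conditions and none higher (camera adjusted p = 0.472).

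**Figure D1:**
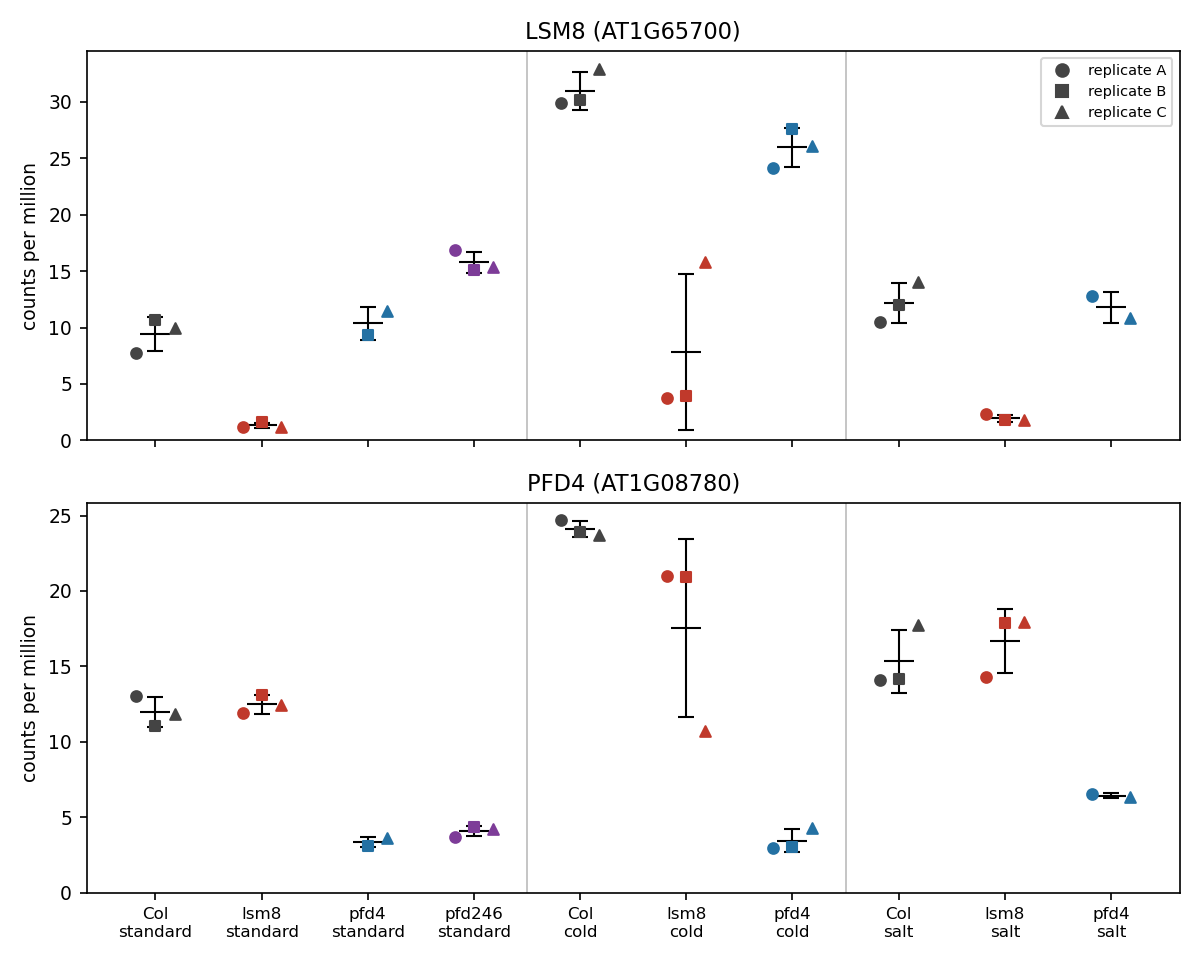
LSM8 (top) and PFD4 (bottom) in CPM for each library in the 10 groups. Each point is 1 library (circle A, square B, triangle C) coloured by genotype, and the black lines give mean and SD. LSM8 lies at 15.8 CPM in the library labelled lsm8 cold replicate C and at 3.79 and 3.92 CPM in the other lsm8 cold libraries.

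Intron retention was higher in lsm8 in each condition. Pooled over 58995 introns, it was 1.72% (SD 0.124, n = 3) in lsm8 and 1.16% (SD 0.0385, n = 3) in Col in standard conditions. It was 2.15% (SD 0.115) and 1.5% (SD 0.0199) in cold, and 1.98% (SD 0.0503) and 1.28% (SD 0.0442) in salt. In each condition all 3 lsm8 libraries lay above all 3 Col libraries, which gives an exact permutation p of 0.1, the smallest that 3 against 3 allows (BH-adjusted 0.14 over the 7 comparisons). In pfd246 it was 1.43% (SD 0.143, n = 3) against 1.2% (SD 0.0405, n = 3) in Col as counted in the same table (exact permutation p = 0.1). In pfd4 it was 1.2% in standard conditions (SD 0.0575, n = 2, exact permutation p = 0.4), 1.38% in cold (SD 0.0388, n = 3, below all Col libraries, exact permutation p = 0.1) and 1.32% in salt (SD 0.0237, n = 2, exact permutation p = 0.3).

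**Figure D2:**
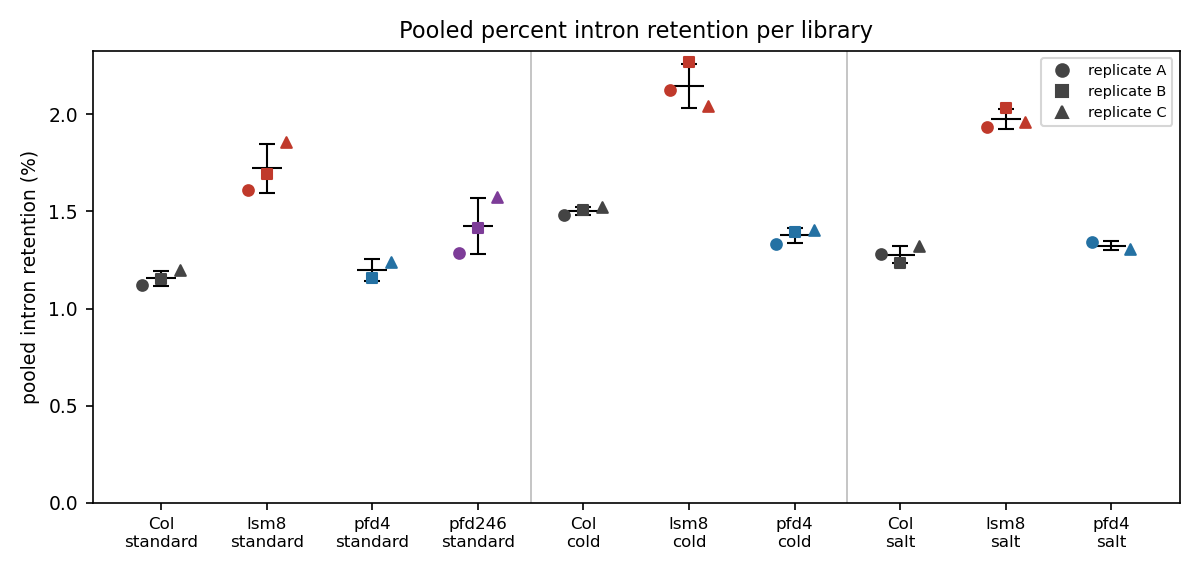
Pooled intron retention in percent for each library, by genotype and condition; points are libraries and the lines give mean and SD. The lsm8 libraries average 1.72%, 2.15% and 1.98% in standard conditions, cold and salt, against 1.16%, 1.5% and 1.28% in Col.

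In lsm8 in standard conditions, 9214 of 20688 genes changed, 4477 up and 4737 down (edgeR). Clock genes were among those that rose: PRR5 (chromosome 5, 8355951 to 8358873), a pseudo-response regulator of the clock, went from 0.280 CPM (SD 0.0843, n = 3) to 5.86 (SD 0.669, n = 3, log2 4.39, SE 0.22, edgeR adjusted p = 4.55e-10). PRR9 went from 40.1 (SD 4.05) to 77.8 CPM (SD 3.54, log2 0.92, SE 0.07). The morning factors LHY (log2 -0.32, SE 0.05) and RVE8 (log2 -0.40, SE 0.05) fell. The largest rises included AT2G18193, from 0.576 to 45.2 CPM (SD 0.226 and 7.15, log2 6.26, SE 0.22, edgeR adjusted p = 8.11e-08). The orphan gene QQS, which affects starch content, went from 4.59 to 47.7 CPM (SD 1.1 and 6.39, log2 3.34, SE 0.19). CASP1, a protein of the Casparian strip of roots, went from 0.289 to 3.58 CPM (SD 0.0388 and 0.586, log2 3.60, SE 0.24). FLC, the repressor of flowering, fell from 2.61 to 0.211 CPM (SD 0.183 and 0.131, log2 -3.65, SE 0.32, edgeR adjusted p = 1.76e-07). Among the largest falls, AT3G01345 (69.1 to 3.05 CPM, SD 18 and 3.47) lost its call without lsm8 standard A (edgeR adjusted p = 0.0548) and with a term for the replicate letter (0.0561). Fold changes rose with transcript length (median log2 -0.23 in genes of up to 934 bases and 0.20 in those of at least 2285 bases, Spearman 0.386 across genes, which are not independent replicates), and 6318 of the 9214 genes were still called with that trend removed.

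By list, 11 of 16 measured clock genes rose and 3 fell (11 and 4 adjusted over the list alone, median log2 0.46, camera adjusted p = 0.0178). Neither this nor the next 2 calls held with an estimated correlation (adjusted p = 0.414, 0.549 and 0.414). Of 14 cold-regulated genes 6 rose and 1 fell (7 and 1 adjusted over the list alone, median log2 0.54, camera adjusted p = 0.0178). Among them were COR15B, which protects chloroplasts in the cold (3.25 to 7.70 CPM, SD 0.366 and 0.547, log2 1.21, SE 0.13), and ERD7 (log2 0.97, SE 0.09). Of 13 LSM and prefoldin subunits 6 fell and none rose (7 fell adjusted over the list alone, camera adjusted p = 0.0397). Examples are LSM1A (log2 -0.34, SE 0.07) and LSM7 (log2 -0.30, SE 0.08). Of 29 splicing factors 13 rose and 2 fell (camera adjusted p = 0.0661). PRP8, a core protein of the spliceosome, stood at 287.8 CPM (SD 9.96) against 186.1 (SD 7.16, log2 0.59, SE 0.05), and the SR protein gene RS40 rose by log2 0.80 (SE 0.07). Of 19 ABA and salt genes 8 rose and 3 fell (camera adjusted p = 0.0821). The phosphatase gene ABI1 rose (42.3 to 77.6 CPM, SD 2.68 and 0.676, log2 0.83, SE 0.06). The dehydrin gene RAB18 fell (log2 -0.58, SE 0.12, a call lost with all 28 libraries in 1 fit at an edgeR adjusted p of 0.199). Of 10 salicylate defence genes 4 rose and 1 fell (camera adjusted p = 0.0821), PR1 most (0.256 to 2.45 CPM, SD 0.102 and 0.314, log2 3.19, SE 0.30). Of 12 flavonoid genes 5 rose and 1 fell (camera adjusted p = 0.0821, and 0.0184 with a term for the replicate letter, where the adjusted p = 0.459 with an estimated correlation). UF3GT had a log2 fold change of 0.92 (SE 0.19). The remaining lists did not pass camera. Of these, 6 of 18 photosynthesis genes fell, led by LHCB5 (log2 -0.27, SE 0.04). In the tubulin and actin list 8 of 22 genes rose and 6 fell. In the others 4 of 9 CCT genes rose, 1 of 12 heat shock genes fell, 1 of 8 jasmonate genes rose and 1 of 11 flowering genes rose while 4 fell. The single measured root marker, CASP1, rose, and no seed marker was measured.

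In lsm8 in standard conditions 7837 of 35784 introns changed in retention, 7801 of them with a rise and 36 with a fall, in 4352 genes (edgeR). In the introns with a rise the median retention was 2.70% in lsm8 against 0.138% in Col. The largest rises had no spliced read left in lsm8. One is the intron at chromosome 1, 2953075 to 2953162 in AT1G09160 (100% against 29.2%, SD 3.87, n = 3, log2 odds 7.88, SE 1.31, edgeR adjusted p = 2.9e-07). The others lie at chromosome 4, 6455242 to 6455325 in AT4G10430 (100% against 30.2%, SD 2.87) and at chromosome 3, 11383676 to 11383923 in AFP3, an ABI5 binding protein gene (100% against 35%, SD 14.3). In ACD5, a ceramide kinase gene, the intron at chromosome 5, 20846077 to 20846165 was retained at 82.1% (SD 31) against 10.9% (SD 2.50, log2 odds 4.25, SE 0.99, edgeR adjusted p = 0.000554). The largest fall that held was in PSRP2, a plastid ribosomal protein gene (chromosome 3, 19343139 to 19343244; 78.1%, SD 4.61, against 98.4%, SD 1.84, log2 odds -4.38, SE 0.64, edgeR adjusted p = 3.38e-09). The count of introns was 4769 with a term for the replicate letter, and 5121, 3822 and 3797 without Col standard A, B or C. Of 1464 exon parts none changed (edgeR; 184 at an unadjusted p under 0.05, 15 calls by limma, and 3 without lsm8 standard A).

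**Figure D3:**
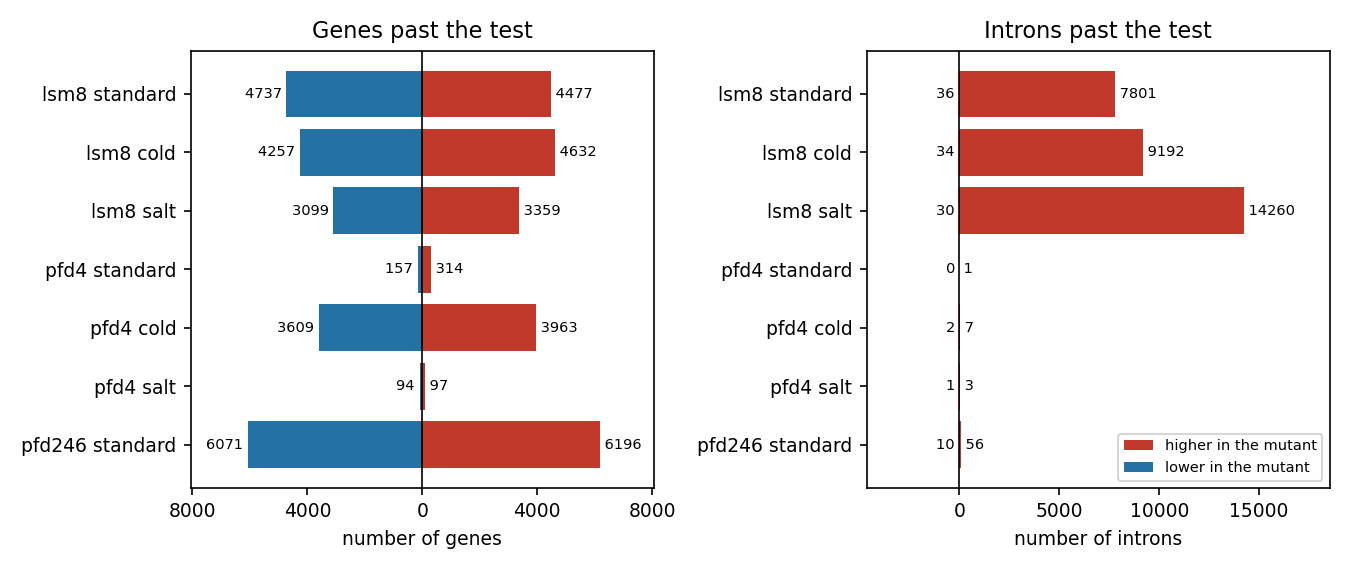
Number of genes (left) and introns (right) that were higher (red) or lower (blue) in the mutant in each of the 7 comparisons with Col; each bar is a count past the edgeR threshold. In lsm8 in standard conditions, 7801 introns were higher and 36 lower.

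In lsm8 in cold, 8889 of 20741 genes changed, 4632 up and 4257 down (edgeR; 9281 without the library labelled lsm8 cold replicate C). AT2G18193 went from 0.565 to 146.6 CPM (SD 0.196 and 55.8, n = 3 each, log2 8.03, SE 0.56, edgeR adjusted p = 0.000638). AT2G04050, which encodes a MATE efflux protein and has a close neighbouring copy, went from 0.541 to 134.6 CPM (SD 0.151 and 60.7, log2 7.97, SE 0.63). UGT74E2, which glycosylates the auxin precursor IBA, went from 1.75 to 75.2 CPM (SD 0.437 and 22.4, log2 5.45, SE 0.36, edgeR adjusted p = 0.000389). GI, a clock gene that acts in the evening, went from 10.6 to 82.1 CPM (SD 2.35 and 7.26, log2 3.01, SE 0.14, edgeR adjusted p = 5.87e-06). PRR5 went from 20.8 to 64.1 CPM (SD 2.97 and 4.70, log2 1.68, SE 0.09). Among the falls were BT2 (73.3 to 20.7 CPM, SD 6.11 and 3.03, log2 -1.76, SE 0.11), AT3G01345 (log2 -7.01, SE 0.33) and CBF2, an activator of cold genes (6.70 to 3.85 CPM, SD 0.775 and 0.402, log2 -0.74, SE 0.13, edgeR adjusted p = 0.000603). The share of reads on plastid genes was 1.27%, 1.13% and 1.48% in the lsm8 cold libraries and 0.399% on average in Col (SD 0.0101, n = 3). CASP1 rose from 1.17 to 3.49 CPM (SD 0.474 and 0.785, log2 1.61, SE 0.29).

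By list, 17 of 29 splicing factors rose in lsm8 in cold and none fell (20 and 0 adjusted over the list alone, camera adjusted p = 5.14e-05). None of the 8 calls here held with an estimated correlation (lowest adjusted p = 0.29). PRP8 stood at 461.8 CPM (SD 47.0) against 275.9 (SD 4.58, log2 0.80). Of 17 clock genes 12 rose and none fell (13 and 0 adjusted over the list alone, camera adjusted p = 5.14e-05). Of 12 flavonoid genes 11 rose and none fell (12 and 0 adjusted over the list alone, camera adjusted p = 0.000175). Examples are PAP1, a regulator of anthocyanin synthesis (7.56 to 16.2 CPM, SD 0.129 and 1.85, log2 1.15, SE 0.10), and FLS1 (log2 0.65, SE 0.07). Of 12 heat shock genes 8 rose and none fell (8 and 1 adjusted over the list alone, camera adjusted p = 0.0162). HSP70-1 stood at 4114 CPM (SD 128.5) against 3272 (SD 145.2, log2 0.39, SE 0.06). Of 13 LSM and prefoldin subunits 8 fell and none rose (camera adjusted p = 0.0113). They include LSM5 (log2 -0.28, SE 0.06) and LSM1A (log2 -0.36, SE 0.08), while fold changes in lsm8 in cold rose with transcript length (median log2 -0.17 in genes of up to 928 bases, 0.18 in those of at least 2279, Spearman 0.291 across genes). Of 10 salicylate defence genes 5 rose (6 up and 1 down adjusted over the list alone, camera adjusted p = 0.025), including PAD3, an enzyme of camalexin synthesis (log2 3.08, SE 0.36), and WRKY70 (log2 1.33, SE 0.17). Of 16 cold-regulated genes 6 rose and 1 fell (camera adjusted p = 0.0324). ZAT12 stood at 14.1 against 3.84 CPM (SD 1.43 and 0.237, log2 1.94, SE 0.10). Of 19 ABA and salt genes 6 rose and 1 fell (camera adjusted p = 0.025). The phosphatase gene HAB1 stood at 114.7 against 60 CPM (SD 5.43 and 4.26, log2 0.99, SE 0.06). Without lsm8 cold C the last 2 lists lost their calls (camera adjusted p = 0.0749 and 0.071). The flowering, photosynthesis, tubulin and actin, CCT, jasmonate and root marker lists did not pass (lowest camera adjusted p = 0.387), with TUA2 up (log2 0.61) and TUB8 (log2 -0.34) and TUB6 (log2 -0.35) down.

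In lsm8 in cold 9226 of 43338 introns changed in retention, 9192 up and 34 down, in 5042 genes (edgeR). The introns with a rise had a median of 2.82% against 0.183% in Col. A large rise was that in AT3G15395 (chromosome 3, 5200758 to 5200850; 100% against 33.8%, SD 12.3, log2 odds 7.62, SE 1.33, edgeR adjusted p = 1.61e-06). Others were those in the kinase gene PK1B (chromosome 2, 12424603 to 12425032; 65.9%, SD 6.42, against 7.37%, SD 1.22, log2 odds 4.60, SE 0.64, edgeR adjusted p = 3.51e-10) and the glucosidase gene BGLU6 (chromosome 1, 22224062 to 22224128; 67.2%, SD 25.8, against 8.22%, SD 2.40). Retention fell in hemf2, a gene of tetrapyrrole synthesis (chromosome 4, 1414335 to 1414425; 37.7%, SD 7.51, against 81.7%, SD 6.56, edgeR adjusted p = 0.00278). The count was 5376, 4378 and 5560 without Col cold A, B or C, and 5699 and 8719 without lsm8 cold B or C. Of 1465 exon parts 2 changed (edgeR, 7 by limma). In the polyubiquitin gene UBQ10 a part was included at 58.4% (SD 4.88) against 2.79% (SD 1.14, log2 odds 5.67, SE 0.39, edgeR adjusted p = 0.00569). This call was lost without Col cold B (0.0711) or lsm8 cold B (0.0665) and with a term for the replicate letter (0.0893). In MLP28 a part stood at 100% against 94.7% (SD 0.899), a call lost without Col cold A (edgeR adjusted p = 0.144), Col cold B (0.239), Col cold C (0.225) or lsm8 cold B (0.0798). The count of exon parts was 0 without Col cold B or lsm8 cold B, 1 without Col cold C and 4 without lsm8 cold A.

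In lsm8 in salt, 6458 of 23044 genes changed, 3359 up and 3099 down (edgeR; 4206 without lsm8 salt C). QQS went from 2.41 to 59.1 CPM (SD 0.306 and 5.71, n = 3 each, log2 4.48, SE 0.11, edgeR adjusted p = 1.95e-08). AT2G01422 went from 0.0991 to 16.9 CPM (SD 0.0860 and 1.49, log2 7.27, SE 0.38) and PRR5 from 1.89 to 10.8 CPM (SD 0.484 and 0.757, log2 2.38, SE 0.17, edgeR adjusted p = 1.86e-05). FLC (2.82 to 0.0544 CPM, SD 0.365 and 0.0242, edgeR adjusted p = 3.8e-06) and AT3G01345 (145.3 to 3.73 CPM, SD 6.64 and 0.960, log2 -5.41, edgeR adjusted p = 2.4e-06) fell. Of 18 photosynthesis genes 10 fell and none rose (14 adjusted over the list alone, median log2 -0.25, camera adjusted p = 1.61e-05). With an estimated correlation this and the next 4 calls were lost (lowest adjusted p = 0.416). Examples are the Rubisco activase gene RCA (8738 to 5858 CPM, SD 580.3 and 357.9, log2 -0.71, edgeR adjusted p = 0.000388). Of 16 heat shock genes 10 fell and none rose (14 adjusted over the list alone, median log2 -0.63, camera adjusted p = 5.72e-05). HSFA2 had a log2 fold change of -0.56 (SE 0.09). Of 22 tubulin and actin genes 8 fell and none rose (median log2 -0.16, camera adjusted p = 0.00203). They include ACT2 (log2 -0.55, SE 0.07) and ACT8 (log2 -0.46). Of 19 ABA and salt genes 3 rose and 7 fell (3 and 11 adjusted over the list alone, median log2 -0.33, camera adjusted p = 0.00916). P5CS1, the first enzyme of proline synthesis, fell from 1840 to 1226 CPM (SD 197.8 and 131.9, log2 -0.72, SE 0.11). Of 17 clock genes 10 rose and 2 fell (11 and 2 adjusted over the list alone, median log2 0.36, camera adjusted p = 0.00541). CCA1 fell (log2 -0.42, SE 0.08).

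The other lists did not pass in lsm8 in salt (lowest camera adjusted p = 0.0718, for flavonoid genes). They had 6 of 29 splicing factors up and 2 down, 1 of 16 cold-regulated genes up and 4 down, and 2 of 7 jasmonate genes up. LOX2 was one of these (369.1 to 702.3 CPM, SD 48.2 and 153.2, log2 0.79, SE 0.16). None of 9 CCT genes changed. Some seed and root transcripts were far higher in the salt libraries of Col than in its libraries from soil. The seed storage genes CRA1 and CRC stood at 0.0318 and 0.0102 CPM in Col in standard conditions. In salt they stood at 58.4 CPM (SD 17.9) and 31.3 CPM (SD 7.79) in Col (n = 3). They stood at 35.7 (SD 22.5) and 24.1 (SD 16.9) in lsm8 (n = 3) and at 19.2 (SD 16.5) and 6.97 (SD 4.90) in pfd4 (n = 2). The root genes CASP1 and PRP3, at 0.289 and 0.0240 CPM in Col in standard conditions, stood in salt at 8.23 (SD 1.27) and 19.6 CPM (SD 8.01) in Col and at 9.34 (SD 1.45) and 23.4 (SD 3.91) in lsm8. Of 6 seed markers 1 rose (2 adjusted over the list alone, camera adjusted p = 0.81). Of 8 root markers none changed (camera adjusted p = 0.563).

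In salt 14290 of 47456 introns changed in retention in lsm8, 14260 up and 30 down, in 7266 genes (edgeR), with medians of 2.54% against 0.223% in Col in the introns with a rise. Large rises were found in AT5G21100 (chromosome 5, 7169677 to 7169750; 63.9%, SD 3.13, against 14.2%, SD 1.5, log2 odds 3.42, SE 0.28, edgeR adjusted p = 1.13e-29) and in AT3G44970 (76.2%, SD 7.11, against 19.3%, SD 2.95). Another was in GORK, which encodes a channel for outward flow of potassium (chromosome 5, 14890749 to 14890814; 76.2%, SD 9.85, against 27.0%, SD 0.304, log2 odds 3.09, SE 0.64, edgeR adjusted p = 6.27e-05). A fall in AT5G14550 (27.8%, SD 4.48, against 52.6%, SD 3.11, log2 odds -1.50, edgeR adjusted p = 0.00025) did not pass at the second border alone (log2 odds -1.09, 0.502). The count was 8758 without Col salt A and 8622 without Col salt B. Of 1877 exon parts 72 changed, 19 with more and 53 with less inclusion in lsm8 (edgeR; 6 by limma; 46, 47 and 44 without Col salt A, Col salt B or lsm8 salt A). Of 292 skipped exons 4 rose and 31 fell, of 525 alternative 5 prime sites 10 rose and 9 fell. Of 1060 alternative 3 prime sites 5 rose and 13 fell. AT5G26740 held a part included at 24% (SD 7.98) against 60.8% (SD 9.98, log2 odds -2.2, SE 0.43, edgeR adjusted p = 0.000264), and AT1G52710 one at 38.7% (SD 9.81) against 9.14% (SD 5.77, log2 odds 2.66, SE 0.51, edgeR adjusted p = 0.000219). Neither passed by limma (adjusted p = 0.0666 and 0.0956).

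In pfd4 in standard conditions (n = 2 against 3), 471 of 21221 genes changed, 314 up and 157 down (edgeR). Of the tubulin and actin genes 12 of 22 fell and none rose (19 and 0 adjusted over the list alone, median log2 -0.35, camera adjusted p = 9.41e-15, adjusted p = 0.244 with an estimated correlation). Examples are TUB6 (115.5 to 82.8 CPM, SD 6.18 and 0.389, log2 -0.50, SE 0.07, edgeR adjusted p = 0.00376) and TUB7 (140.4 to 103.3 CPM, SD 3.54 and 2.76, log2 -0.46, SE 0.07). Of 12 flavonoid genes 9 rose and none fell (11 adjusted over the list alone, median log2 0.90, camera adjusted p = 5.3e-11, adjusted p = 0.31 with an estimated correlation). Examples are CHI, chalcone isomerase (53.1 to 78.5 CPM, SD 1.95 and 1.51, log2 0.55, SE 0.07). Of 8 jasmonate genes 3 rose (5 adjusted over the list alone, camera adjusted p = 0.00176, adjusted p = 0.31 with an estimated correlation). LOX2, a lipoxygenase of jasmonate synthesis, stood at 571.7 CPM (SD 14.3) against 311.5 (SD 41.2, log2 0.86, SE 0.10). The myrosinase-binding protein gene MBP1 went from 15.4 to 94.4 CPM (SD 3.17 and 1.42, log2 2.61, SE 0.13, edgeR adjusted p = 3.85e-06). PR1 went from 0.256 to 3.58 CPM (SD 0.102 and 1.04, log2 3.76, SE 0.32), and MAF5, a relative of FLC, from 0.729 to 4.68 CPM (SD 0.155 and 1.58). FLC rose as well (2.61 to 6.51 CPM, SD 0.183 and 0.950, log2 1.29, SE 0.15, edgeR adjusted p = 0.000502). The wax ester synthase gene WSD1 fell from 24.7 to 7.57 CPM (SD 3.54 and 0.149, log2 -1.72), MRD1 from 10.2 to 0.0872 CPM (SD 3.05 and 0.123) and AT3G01345 by log2 -7.53 (edgeR adjusted p = 0.013).

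Of the other lists in pfd4 in standard conditions, salicylate defence (1 of 10 up, 3 adjusted over the list alone, camera adjusted p = 0.00163), heat shock (2 of 12 up, camera adjusted p = 0.0262) and flowering (3 of 11 up and 1 down, 4 and 1 adjusted over the list alone, camera adjusted p = 0.0307) passed. None held with an estimated correlation. The remaining lists did not pass (lowest camera adjusted p = 0.0657, for photosynthesis). FLC, PR1 and LOX2 lost their calls when all 28 libraries were fitted together (edgeR adjusted p = 0.232, 0.104 and 0.084). AT3G01345 lost its call without Col standard B (0.0908), Col standard C (0.106) or pfd4 standard C (0.0606) and with a term for the replicate letter (0.18). The count of genes was 1457 with a term for the replicate letter, 715 by DESeq2, 723 with no filter on low counts, 286 without Col standard B and 251 without pfd4 standard C. Of 22357 introns 1 changed in retention (edgeR, 1089 at an unadjusted p under 0.05, 0 by limma). The count was 2 without Col standard A, 3 without pfd4 standard B and 0 without Col standard B, Col standard C or pfd4 standard C. Of 1501 exon parts none changed (edgeR; 46 at an unadjusted p under 0.05, 0 by limma, 1 without Col standard A).

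In pfd4 in cold (n = 3 against 3), 7572 of 20442 genes changed, 3963 up and 3609 down (edgeR). Ribosomal RNA loci and plastid reads were higher as well, AT2G01010 at 3052 CPM (SD 493.2) against 995.4 (SD 53.6) and plastid reads at 0.810% (SD 0.203) against 0.399% (SD 0.0101). Of 21 tubulin and actin genes 14 fell and 4 rose (median log2 -0.19, camera adjusted p = 0.019). None of the 7 calls given here held with an estimated correlation (lowest adjusted p = 0.246). TUB9 went from 224.4 to 140.6 CPM (SD 11.5 and 7.10, log2 -0.56, SE 0.05, edgeR adjusted p = 1.51e-06). TUB7 fell by 0.39 on the log2 scale, and TUA2 (log2 0.42) and TUA6 (log2 0.35) rose. Of 11 flavonoid genes 10 rose and none fell (median log2 0.79, camera adjusted p = 3.14e-07). Among them were F3H (242.1 to 351.3 CPM, SD 5.61 and 12.1, log2 0.65, SE 0.05). Of 13 LSM and prefoldin subunits 9 fell and none rose (median log2 -0.25, camera adjusted p = 0.00128). Fold changes in pfd4 in cold rose with transcript length (median log2 -0.21 in genes of up to 932 bases, 0.15 in those of at least 2283, Spearman 0.333 across genes). LSM7 stood at 20.4 against 29.2 CPM (SD 1.39 and 2.52, log2 -0.40, SE 0.07). Of 18 photosynthesis genes 7 rose and none fell (camera adjusted p = 0.019). RBCS2B stood at 2586 against 1378 CPM (SD 306.4 and 72.3, log2 1.02, SE 0.09). For the clock 8 of 17 genes rose and 1 fell (camera adjusted p = 0.0239). PRR9 had a log2 fold change of 1.26 (SE 0.13), and 4 of 10 salicylate defence genes rose (camera adjusted p = 0.0249). WRKY70 had a log2 fold change of 0.90 (SE 0.14). Of 29 splicing factors 11 rose and 2 fell (11 and 3 adjusted over the list alone, camera adjusted p = 0.0239), though the median turned negative on the CPM scale, with PRP8 at log2 0.57 and SR34B at log2 -0.84.

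Other genes of pfd4 in cold with large changes were MBP1 (20.0 to 101.6 CPM, SD 2.55 and 8.51, log2 2.46, SE 0.10, edgeR adjusted p = 3.41e-07), the cellulose synthase-like gene CSLA01 (0.675 to 10.3 CPM, SD 0.0428 and 3.75), MAF5 (0.864 to 4.62 CPM, SD 0.377 and 0.450, log2 2.54, SE 0.24) and AT2G18193 (0.565 to 10.1 CPM, SD 0.196 and 0.510, log2 4.23, SE 0.19). The falls included MRD1 (12.2 to 0.221 CPM, SD 3.68 and 0.125, log2 -5.68, SE 0.40), HEI10, a gene of meiotic crossing over that overlaps MRD1 (log2 -3.17), and AT3G01345 (log2 -8.01). Of 16 cold-regulated genes 1 rose and 3 fell (camera adjusted p = 0.0709), COR15A (8018 to 5313 CPM, SD 656.5 and 708.5, log2 -0.48, SE 0.09) and CBF2 (6.70 to 3.38 CPM, SD 0.775 and 0.538, log2 -0.86, SE 0.14) among the falls. Of 19 ABA and salt genes 1 rose and 6 fell (camera adjusted p = 0.0575). The vacuolar sodium exchanger gene NHX1 stood at 65.5 against 104.3 CPM (SD 3.25 and 5.10, log2 -0.56, SE 0.05). The flowering (2 up, 4 down), CCT (4 of 9 up, with a median that turns negative on the CPM scale), heat shock, jasmonate and root marker lists did not pass (lowest camera adjusted p = 0.0707). The plastid share was 0.88%, 0.58% and 0.97% in the pfd4 cold libraries.

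In pfd4 in cold 9 of 26213 introns changed in retention, 7 up and 2 down (edgeR; 1 by limma). The clearest lay in PFD4 itself: the intron of 88 bases at chromosome 1, 2811027 to 2811114 had no spliced read in the 3 pfd4 cold libraries (29, 25 and 32 border reads; 100% against 1.06%, SD 0.482, in Col, log2 odds 13.74, SE 1.03, edgeR adjusted p = 6.86e-36). In CR88, a chloroplast HSP90 gene, an intron was retained at 0.731% (SD 0.130) against 0.0304% (SD 0.0282, edgeR adjusted p = 2.23e-05, limma 0.51). The count was 4, 2 and 3 without Col cold A, B or C and 16 without pfd4 cold B. Of 1383 exon parts 2 changed (edgeR; 6 by limma), in AT5G57290 (100% against 82.7%, SD 0.818) and in CYSC1 (100% against 97.0%, SD 0.714). Both lost their calls with a term for the replicate letter (edgeR adjusted p = 0.171 for each). The count was 0 without any 1 of the Col cold libraries, 5 without pfd4 cold A, 4 without B and 1 without C.

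In pfd4 in salt (n = 2 against 3), 191 of 22876 genes changed, 97 up and 94 down (edgeR). MBP1 went from 18.5 to 303.5 CPM (SD 4.33 and 30.6, log2 3.97, SE 0.21, edgeR adjusted p = 0.00325) and the cellulose synthase-like gene CSLA10 from 17.0 to 90.8 CPM (SD 1.37 and 3.55, log2 2.35, SE 0.09, edgeR adjusted p = 7.02e-05). AT3G01345 fell from 145.3 to 0.391 CPM (SD 6.64 and 0.0600, log2 -8.60, SE 0.14) and HEI10 from 24.7 to 2.18 CPM (SD 2.2 and 0.413, log2 -3.56, SE 0.15). Of 23 tubulin and actin genes 5 fell and none rose (20 adjusted over the list alone, median log2 -0.43, camera adjusted p = 8.21e-14). This and 8 other list calls were lost with an estimated correlation (lowest adjusted p = 0.277). TUB5 stood at 29.7 against 57.3 CPM (SD 2.17 and 4.03, log2 -1.01, SE 0.09, edgeR adjusted p = 0.00773, and 0.0548 without Col salt B). Of 12 flavonoid genes 2 rose (10 adjusted over the list alone, median log2 1.51, camera adjusted p = 9.87e-08) and of 7 jasmonate genes 2 rose (6 adjusted over the list alone, camera adjusted p = 8e-06). LOX2 stood at 1291 against 369.1 CPM (SD 288.9 and 48.2, log2 1.74, SE 0.16, edgeR adjusted p = 0.00899, but 0.0558 and 0.0502 without Col salt B or C and 0.054 with a term for the replicate letter). Of 16 heat shock genes 1 fell (7 adjusted over the list alone, median log2 -0.57, camera adjusted p = 3.53e-06). The cold-regulated (none over all genes, 2 down adjusted over the list alone), ABA and salt (none), CCT (none), photosynthesis (3 down adjusted over the list alone) and flowering (1 up, 5 up and 1 down adjusted over the list alone) lists passed camera too (adjusted p = 0.00347, 0.0233, 0.0165, 0.0187 and 0.0314). None of 8 root markers and 6 seed markers changed (camera adjusted p = 0.858 and 0.0785).

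The count of genes in pfd4 in salt rested on single libraries: it was 56 without Col salt A, 8 without Col salt B, 70 without pfd4 salt A and 819 without pfd4 salt C. It was 1872 by DESeq2, 3007 with all 28 libraries in 1 fit, 471 with no filter on low counts and 51 with a term for the replicate letter. Of 28003 introns 4 changed in retention, 3 up and 1 down (edgeR; 1 by limma; 2 without Col salt B, 2 without Col salt C and 1 without pfd4 salt A). The PFD4 intron was again the largest (84.0%, SD 0.453, n = 2, against no border read in Col, log2 odds 13.47, SE 0.88, edgeR adjusted p = 2.77e-48). Of 1879 exon parts none changed (edgeR; 122 at an unadjusted p under 0.05, 0 by limma, 1 without Col salt C).

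In pfd246 in standard conditions (n = 3 against 3), 12267 of 21257 genes changed, 6196 up and 6071 down (edgeR). All 10 salicylate defence genes rose (median log2 2.96, camera adjusted p = 7.87e-07). Neither this call nor those of the next 4 lists held with an estimated correlation (adjusted p = 0.421 for each). Among them were PAD4 (7.18 to 94.3 CPM, SD 0.914 and 3.13, log2 3.45, SE 0.09, edgeR adjusted p = 1.81e-14) and its partner EDS1 (21.5 to 150.9 CPM, SD 0.505 and 13.0, log2 2.54, SE 0.08), both needed for basal resistance. All 18 photosynthesis genes fell (median log2 -1.03, camera adjusted p = 6.2e-09). Examples are the antenna genes LHCB3 (5004 to 2095 CPM, SD 63.9 and 222.9, log2 -1.53, SE 0.08) and LHCA4 (4978 to 2394 CPM, SD 125.1 and 66.2). Of 23 tubulin and actin genes 21 fell and 1 rose (median log2 -0.66, camera adjusted p = 3.39e-07). TUB5 stood at 27.7 against 56.6 CPM (SD 3.0 and 1.79, log2 -1.31, SE 0.08), ACT11 at 28.5 against 65.7 CPM (SD 1.73 and 1.83, log2 -1.48, SE 0.07) and the pollen actin gene ACT12 rising (log2 2.86). Of 13 heat shock genes 10 fell and 1 rose (median log2 -1.11, camera adjusted p = 0.00112). HSP70-4 stood at 24.1 against 129.3 CPM (SD 1.94 and 11.9, log2 -2.70, SE 0.08) and HSP101 at log2 -1.61 (SE 0.09). Of 13 LSM and prefoldin subunits 8 rose and none fell (median log2 0.34, camera adjusted p = 0.0309), PFD5 from 16.4 to 31.2 CPM (SD 0.273 and 1.13, log2 0.65, SE 0.07) and LSM6B by log2 0.58 (SE 0.07).

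The other lists did not pass in pfd246 (lowest camera adjusted p = 0.086). Of 14 cold-regulated genes 5 rose and 5 fell, ZAT12 up (log2 3.49, SE 0.39) and COR47 down (log2 -0.84, SE 0.06). Of 29 splicing factors 12 rose and 1 fell. Of 19 ABA and salt genes 7 rose and 3 fell, with the sodium transporter gene HKT1 down (log2 -1.39, SE 0.16). Of 16 clock genes 6 rose and 5 fell. Of 12 flavonoid genes 6 rose and 1 fell (8 and 1 adjusted over the list alone). Of 9 CCT genes 1 fell. Of 11 flowering genes 3 rose and 2 fell: MAF5 went from 0.729 to 11.9 CPM (SD 0.155 and 0.290, log2 3.78, SE 0.15) and FLC from 2.61 to 14.4 CPM (SD 0.183 and 0.106, edgeR adjusted p = 5.45e-11). The largest rises include AT2G35570 (0.0525 to 24.2 CPM, SD 0.0356 and 1.02, log2 8.65, SE 0.20, edgeR adjusted p = 5.95e-15) and AT2G04050 (0.668 to 139.9 CPM, SD 0.497 and 12.1, log2 7.57). Large falls included AT2G22960 (12.7 to 0.173 CPM, SD 3.39 and 0.0172, log2 -6.47, SE 0.28), the carboxypeptidase-like gene SCPL12 (35.4 to 1.00 CPM, SD 4.72 and 0.479, log2 -5.34) and AT5G13240 (40.3 to 1.61 CPM, SD 1.62 and 0.194, log2 -4.92, SE 0.10).

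In pfd246 66 of 27988 introns changed in retention, 56 up and 10 down, in 64 genes (edgeR; 4 by limma). They include PBS3, a gene of salicylate synthesis (chromosome 5, 4267593 to 4268891; 100% against 16.1%, SD 9.52, log2 odds 10.71, SE 1.24, edgeR adjusted p = 1.03e-13), the PFD4 intron named above (62.2%, SD 13.5, against 0.513%, SD 0.888, edgeR adjusted p = 3.27e-20) and an intron of AT3G47910 (chromosome 3, 17678483 to 17678637; 36.6%, SD 4.40, against no border read in Col, log2 odds 8.64, SE 1.02). Retention fell in PAD4 (chromosome 3, 19431857 to 19432957; 12.7%, SD 1.02, against 66.4%, SD 12.7, log2 odds -3.76, SE 0.64, edgeR adjusted p = 1.33e-05, limma 0.0792) and in CYP71A13, a gene of camalexin synthesis (62.8%, SD 21.2, against 99.5%, SD 0.447, edgeR adjusted p = 1.89e-12, limma 0.11). The count was 20 and 30 without Col standard B or C and 24 without pfd246 B, as without pfd246 C. Of 1511 exon parts 1 changed (edgeR; 1 by limma): a part of TFIIIA, which encodes the transcription factor of 5S rRNA genes, was included at 36.9% (SD 3.07) against 89.4% (SD 1.55, log2 odds -3.84, SE 0.25, edgeR adjusted p = 0.00361, 0.0531 without Col standard C and 0.0871 with a term for the replicate letter). That count was 3, 2 and 0 without Col standard A, B or C, and 2 without pfd246 A or pfd246 C.

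**Figure D4:**
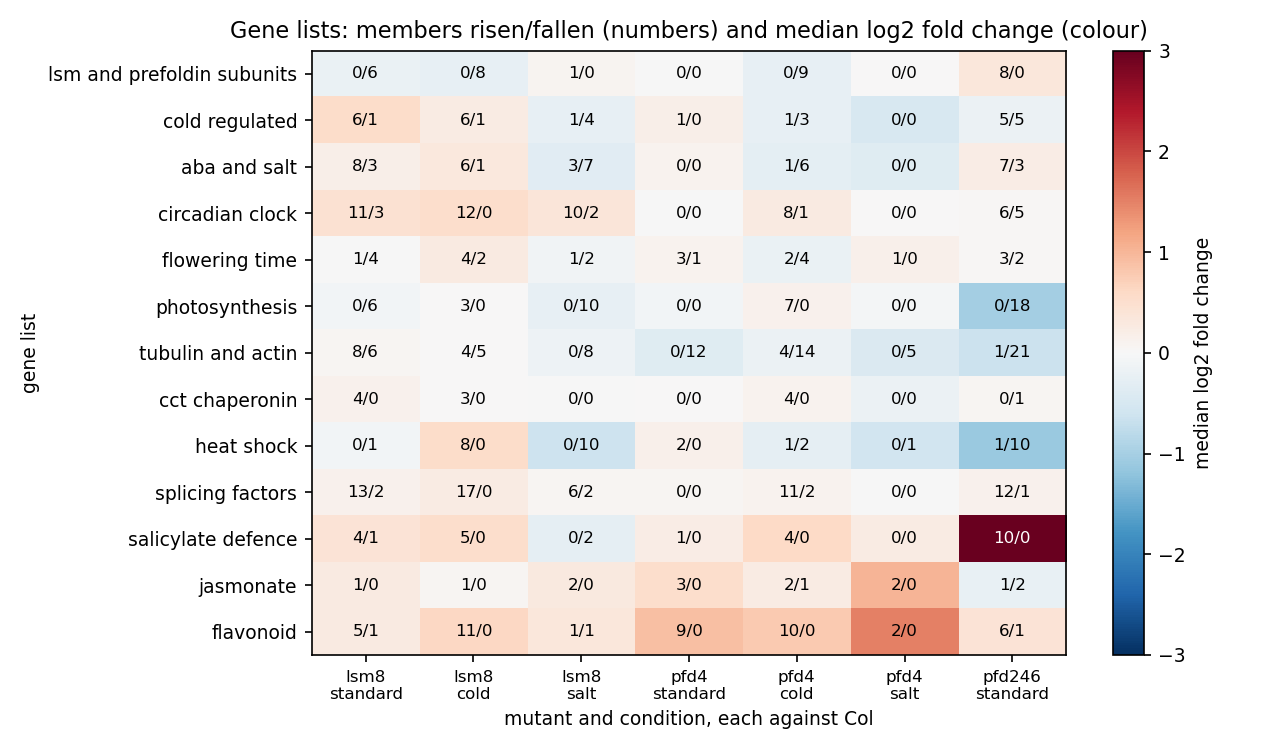
Heat map of 13 gene lists (vertical) against the 7 comparisons with Col (horizontal); the numbers give members that rose and fell, and the colour gives the median log2 fold change on the TMM scale from -3 to 3. On the CPM scale the median changes sign for the flowering list in lsm8 in standard conditions; photosynthesis, tubulin and actin, and CCT in lsm8 in cold; flowering and CCT in lsm8 in salt; LSM and prefoldin subunits and clock in pfd4 in standard conditions; CCT and splicing factors in pfd4 in cold; splicing factors in pfd4 in salt; and cold-regulated genes and jasmonate in pfd246.

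Set directly against pfd4 in standard conditions (n = 3 against 2), pfd246 differed in 10073 genes, 5014 higher and 5059 lower (edgeR). Salicylate defence genes were higher (median log2 2.33, camera adjusted p = 1.37e-06), as were LSM and prefoldin subunits (median log2 0.39, camera adjusted p = 0.00537). These and the next 4 calls did not hold with an estimated correlation (lowest adjusted p = 0.426). Photosynthesis (median log2 -0.96, camera adjusted p = 3.21e-09), heat shock (median log2 -1.36, camera adjusted p = 3.16e-05), tubulin and actin (median log2 -0.39, camera adjusted p = 0.000692) and jasmonate genes (camera adjusted p = 0.0223) were lower. MRD1 stood at 28.9 CPM (SD 1.74) in pfd246 and 0.0872 (SD 0.123) in pfd4 (log2 7.92, SE 0.31, edgeR adjusted p = 9.2e-10), and AT5G13240 was lower in pfd246 (log2 -4.73, SE 0.12). Of 16079 introns 11 differed, 9 with higher and 2 with lower retention in pfd246 (edgeR; 1 by limma; 7 and 3 without pfd4 standard B or C, 3 and 5 without pfd246 B or C). Among them were the AT3G47910 intron (51.6%, SD 3.77, against no border read, edgeR adjusted p = 3.29e-10).

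In Col, 1 day of cold changed 14568 of 20874 genes, 7286 up and 7282 down (edgeR, n = 3 against 3). All 16 cold-regulated genes rose (median log2 6.12, camera adjusted p = 2.86e-09). With an estimated correlation neither this nor the other 5 lists given here passed (lowest adjusted p = 0.228). COR15A went from 18.6 to 8018 CPM (SD 1.82 and 656.5, log2 8.74, SE 0.10, edgeR adjusted p = 9.71e-16). COR15B went from 3.25 to 2796 CPM (SD 0.366 and 170.0), LTI30 from 0.833 to 529.9 CPM (SD 0.354 and 219.3) and CBF2 from 0.186 to 6.70 CPM (SD 0.126 and 0.775, log2 5.03, SE 0.26). CBF1 had no read in the Col standard libraries and stood at 0.479 CPM (SD 0.117) in cold. All 9 CCT genes rose (median log2 1.06, camera adjusted p = 3.75e-05), 11 of 13 LSM and prefoldin subunits rose (median log2 0.49, camera adjusted p = 0.00312). For photosynthesis 13 of 18 genes fell and 2 rose (camera adjusted p = 0.00287), 12 of 17 clock genes rose and 4 fell (camera adjusted p = 0.0449), and 19 of 29 splicing factors rose and 7 fell (camera adjusted p = 0.0449). The regulator WRKY70 fell from 73.0 to 3.58 CPM (SD 5.97 and 0.399). Of 28032 introns 945 changed in retention, 757 up and 188 down (edgeR; 53 by limma). Among them were one of the clock gene RVE8 (chromosome 3, 2948297 to 2948569; 73.3%, SD 5.33, against 6.33%, SD 0.902, log2 odds 5.33, SE 0.38, edgeR adjusted p = 1.8e-40) and one of the polyubiquitin gene UBQ11 (100% against 33.7%, SD 8.32). The count was 516 and 563 without Col cold B or C and 528 and 509 without Col standard B or C.

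The lsm8 effect differed between cold and standard conditions for 2708 genes (edgeR; 2900 without lsm8 cold C, lists untested). The heat shock list was higher in cold, 8 of 13 members up and none down (median log2 0.66, camera adjusted p = 0.00445). So was the flavonoid list (2 up, 3 adjusted over the list alone, camera adjusted p = 0.0289). Neither held with an estimated correlation (adjusted p = 0.815 and 0.893). UGT74E2 (log2 4.48, SE 0.64, edgeR adjusted p = 0.00256) and DTX1, a MATE efflux gene (log2 4.20, SE 0.66), had larger effects in cold, and PRR5 a smaller one (log2 -2.72, SE 0.23, edgeR adjusted p = 2.54e-07). Between salt and standard conditions the lsm8 effect differed for 4363 genes, 2440 up and 1923 down (55.9% up, but 44.8% with RLE factors and 44.4% by DESeq2). Cold-regulated (7 down, median log2 -0.67, camera adjusted p = 0.000162), ABA and salt (7 down), heat shock (3 down, 6 adjusted over the list alone), photosynthesis (6 down), tubulin and actin (7 down, 1 up) and salicylate defence genes (2 down) had lower effects in salt and LSM and prefoldin subunits (3 up) higher ones (camera adjusted p at most 0.00743, but at least 0.399 with an estimated correlation). RAP2.6, an ERF transcription factor gene, differed between the conditions (log2 5.33, SE 0.91, edgeR adjusted p = 0.00231), at 43.5 CPM in lsm8 and 19.1 in Col in salt but only 0.0157 and 0.341 CPM in standard conditions. Introns whose response to lsm8 differed were 1 for cold (0 by limma; 0 without Col standard B, Col standard C, lsm8 cold C or lsm8 standard A) and 17 of 39883 for salt, 3 up and 14 down (edgeR; 5 by limma). The latter count was 5 and 9 without Col standard B or C, 9 and 8 without Col salt A or C, 8 without lsm8 standard A, lsm8 standard B or lsm8 salt A, and 6 without lsm8 salt B or C.

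For pfd4 the effect in cold differed from that in standard conditions in 2586 genes (edgeR). Photosynthesis genes had higher effects in cold (7 up, 9 adjusted over the list alone, median log2 0.28, camera adjusted p = 0.000206), as had tubulin and actin genes (4 up, 8 adjusted over the list alone, median log2 0.16, camera adjusted p = 0.000879) and clock genes (3 up, 1 down, 4 and 1 adjusted over the list alone, median log2 0.28, camera adjusted p = 0.00639). These 3 calls and the next 3 did not hold with an estimated correlation (lowest adjusted p = 0.218). Lower effects in cold were found for LSM and prefoldin subunits (1 down, median log2 -0.20, camera adjusted p = 0.00639), ABA and salt genes (3 down, median log2 -0.35, camera adjusted p = 0.0121) and flowering genes (4 down, median log2 -0.31, camera adjusted p = 0.0256). The rRNA gene AT2G01010 had a larger effect in cold (log2 2.58, SE 0.22, edgeR adjusted p = 0.000142), and APC11 had a lower effect in cold (log2 -2.22, SE 0.25). Between salt and standard conditions the pfd4 effect differed for 41 genes (edgeR; 623 by DESeq2, 67 with no filter on low counts; 9, 11, 21, 101, 10, 11 and 402 without Col standard A, Col standard B, Col salt B, Col salt C, pfd4 standard B, pfd4 standard C or pfd4 salt C). Heat shock genes had lower effects in salt (none over all genes, 12 down adjusted over the list alone, median log2 -0.77, camera adjusted p = 1.66e-08). For this list and the next 6 the lowest adjusted p with an estimated correlation was 0.776. So had cold-regulated (median log2 -0.51), ABA and salt (median log2 -0.44), CCT (median log2 -0.19, camera adjusted p = 0.00611 for each of these 3) and splicing factor genes (median log2 -0.18, camera adjusted p = 0.021). Jasmonate genes (5 up and 1 down adjusted over the list alone, median log2 0.88, camera adjusted p = 0.00902) and flavonoid genes (median log2 0.47, camera adjusted p = 0.0329) had higher ones. No intron passed either pfd4 interaction (edgeR; 1718 and 898 at an unadjusted p under 0.05 for cold and salt, 0 by limma; 1 for cold without pfd4 cold B, and 1 for salt without Col standard B, Col standard C or pfd4 standard B).

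In cold, lsm8 and pfd4 changed 4258 genes in the same direction, against 1627 for independent lists, and 312 in opposite directions. Without lsm8 cold C, which lies between lsm8 and pfd4 in both mutated genes, they were 4101 against 1686, with 503 opposite. In standard conditions lsm8 and pfd246 shared 4103 genes in direction against 2655 (1749 opposite), lsm8 and pfd4 203 against 102 (87 opposite), and pfd4 and pfd246 329 against 133 (69 opposite). In salt lsm8 and pfd4 shared 53 against 25.9 (21 opposite), and 516 by DESeq2. With independent changes simulated in mutants that share Col libraries, 1308 genes on average were shared in cold (10 simulations, highest 1364; 7416 and 6234 calls against 8762 and 7561 in the data). For the standard pairs the means were 2383, 97.3 and 125 (highest 2459, 102 and 136), and in salt 22.7 (highest 28). Groups simulated without change shared 0 genes, with at most 1 call each, and the covariance of the log2 fold changes exceeded theirs by 0.116 for lsm8 and pfd4 in cold, by 0.136, 0.028 and 0.105 for the 3 standard pairs and by 0.0146 in salt. For introns lsm8 and pfd246 shared 31 against 9.64 for independent lists, lsm8 and pfd4 shared 6 against 1.35 in cold, 1 against 0.546 in salt and 0 against 0.186 in standard conditions, and pfd4 and pfd246 0 against 0.00227 (0 without change), with 0 shared in each of the first 3 of these pairs by limma. With independent changes (4 simulations) the means were 7.5 for lsm8 and pfd246 (28.5 pfd246 calls against 58), 0.5, 0.75, 0 and 0. The Col libraries cannot be split between the mutants and may give part of each excess. In cold so may the length trend of both mutants, which neither baseline holds.

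The share of junction reads on unannotated junctions was lower in pfd246 (2.39%, SD 0.104, n = 3) than in Col (4.09%, SD 0.170, n = 3), with all 3 libraries below all 3 (exact permutation p = 0.1, BH-adjusted 0.175). Without the 10234 of 136606 unannotated junctions that join 2 genes it was 1.3% against 1.31%. In lsm8 the share was 3.78% (SD 0.408) in standard conditions (exact permutation p = 0.3), 3.40% (SD 0.130) against 3.24% (SD 0.0356) in cold (exact permutation p = 0.1) and 0.970% (SD 0.0461) against 0.938% (SD 0.0148) in salt (exact permutation p = 0.4). In pfd4 it was 3.99% in standard conditions (exact permutation p = 0.6), 3.12% (SD 0.0360) in cold (exact permutation p = 0.1) and 0.975% in salt (exact permutation p = 0.1). With the same threshold of 0.05 on their adjusted p, the authors' deposited test tables list 9129, 8664 and 6369 genes and 6851, 7901 and 14928 introns for lsm8 in standard conditions, cold and salt, 953, 7646 and 1515 genes and 12, 2976 and 35 introns for pfd4, and 11747 genes and 2473 introns for pfd246.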

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

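The tests of the library labelled lsm8 cold replicate C, of unannotated junctions, of directions shared with other comparisons and of other splits of the libraries were chosen after these results were seen, while the predictions for transcript length and depth in pfd4 in cold were written before.

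The effects of a mutant that differed between conditions by the interaction test (edgeR, BH-adjusted) were 2708 genes and 1 intron for lsm8 in cold, 4363 genes and 17 introns for lsm8 in salt, 2586 genes for pfd4 in cold and 41 genes for pfd4 in salt, each against standard conditions. For lsm8 in cold the extremes were AT2G04070 (log2 5.22, SE 1.11, edgeR adjusted p = 0.0172, and 0.0512 without Col cold A or 0.0518 without Col standard A) and AT5G23240 (log2 -4.01, SE 0.25, edgeR adjusted p = 2.94e-09), which overlaps AT5G23235 (log2 -2.78). The single intron, in the chromatin protein gene HMGB1, had a log2 odds difference of -8.71 (SE 1.55, edgeR adjusted p = 0.0116), with retention of 72.2% (SD 24.3) in lsm8 and 100% in Col in cold and 78.7% (SD 19.0) and 72.9% (SD 24.2) in standard conditions. It lost its call without Col standard B (edgeR adjusted p = 0.466), Col standard C (0.0688), lsm8 cold C (0.289) or lsm8 standard A (0.95). For lsm8 in salt they were ACS7 (log2 5.95, SE 1.69, edgeR adjusted p = 0.0285), AT2G16005 (log2 -6.56, SE 1.04, edgeR adjusted p = 0.000761), and introns of AT5G27950 (log2 odds 7.82, SE 1.77, edgeR adjusted p = 0.0376) and MLO11 (log2 odds -7.58, SE 1.78, edgeR adjusted p = 0.0497). In salt ACS7 stood at 18 CPM in lsm8 and 7.96 in Col, and in standard conditions at 0 in lsm8 and 0.0547 in Col. AT2G16005 stood at 12.9 CPM in lsm8 and 31.2 in Col in salt, and at 0.0703 in lsm8 and 0 in Col in standard conditions, so that the size of both log2 differences rests on a group with no reads. ACS7 lost its call without Col standard B (edgeR adjusted p = 0.135) or lsm8 standard A (0.0628), B (0.0635) or C (0.0554). The AT5G27950 intron lost its call without any 1 library but Col standard A and Col salt A (edgeR adjusted p from 0.0782 to 0.204), and the MLO11 intron without any 1 library but Col standard A (0.0958 to 0.408). For pfd4 in cold they were the rRNA locus AT2G01021 (log2 2.83, SE 0.48, edgeR adjusted p = 0.0103), one of several near-identical copies, and the small RNA precursor TAS1C (log2 -2.50, SE 0.35, edgeR adjusted p = 0.00223). For pfd4 in salt they were FTM1 (log2 2.73, SE 0.43, edgeR adjusted p = 0.0473) and PRN (log2 -1.87, SE 0.20, edgeR adjusted p = 0.00619). FTM1 lost its call without any 1 library but Col salt C, pfd4 salt A and pfd4 salt C (edgeR adjusted p from 0.0554 to 0.26). The salt differences also carry the medium, the alignment and the root and seed levels given above.

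Of 100 library splits, the real one included, 3 gave at least the real 2708 genes for the lsm8 and cold interaction (highest other 3378). For salt 2 gave at least 4363 (highest other 4505). Of the others 16 and 15 called genes. Splits that keep lsm8 and Col apart in 1 condition carry the lsm8 effect, so chance stays undecided. Of 24 splits, 7 gave as many introns for cold as the real 1 (highest other 406). For salt 2 gave as many as 17 (highest other 138). The same limit holds. The pairs of 3 against 3 libraries allow only 10 splits, too few for a share under 0.05. The real and highest other counts were 9214 and 0 genes for lsm8 in standard conditions, 8889 and 0 in cold, 6458 and 0 in salt, 7572 and 0 for pfd4 in cold, 12267 and 0 for pfd246 and 14568 and 0 for cold in Col. For introns they were 7837 and 1, 9226 and 1, 14290 and 0, 9 and 1, 66 and 3, and 945 and 4 in the same order, and for exon parts 0 and 0, 2 and 0, 72 and 0, 2 and 1, and 1 and 1 for the first 5 of these.

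The library labelled lsm8 cold replicate C stood apart in both mutated genes and may be a mixture of lsm8 and pfd4 material: from the mean of lsm8 A and B towards the pfd4 mean it lay 54.1% of the way for LSM8, 58.4% for PFD4 and 34.2% for pooled retention of the 7801 introns raised in lsm8. A mixture with Col material was excluded by PFD4, at 10.7 CPM below both the lsm8 and the Col levels, and a wholly exchanged pfd4 library by retention, at 1.28% against 1.57% and 1.63% in lsm8 A and B and 0.664% in pfd4. The PFD4 intron without spliced reads in pfd4 had 20 border reads and 96 spliced reads in C (9.43%), against 0.412% and 1.67% in A and B. Over 78 genes the median position was 45.5% of the way (quartiles 28.3 and 53.5), against 2.47 for B from A. No biological explanation was tested.

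Genes changed in pfd4 in cold far outnumber those of the other pfd4 comparisons, and neither technical explanation tested could account for most of them. With a trend with transcript length removed 6434 genes were called, 5434 of them among the 7572, and with the Col cold libraries thinned to 36.8 M reads 7269. A shift of the Col cold libraries away from both mutants stays open. Of the genes 81.6% (6169 of 7563) moved the same way in lsm8 in cold without its replicate C. In 20 simulations with lsm8 unchanged and the same Col libraries it was 57.7%. Effects or a length trend shared by lsm8 and pfd4 would give an excess as well. As a biological comparison, 65% (4889 of 7526) moved the same way in pfd4 in standard conditions and 50.6% (3824 of 7550) as cold moves them in Col. The higher rRNA (AT2G01010 at 3052 against 995.4 CPM) and plastid reads (0.810% against 0.399%) of pfd4 in cold were not tested as a cause.

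The lower share of unannotated junction reads in pfd246 (-1.70 percentage points) lies on junctions that join 2 genes, since without them the difference was -0.00883. On those junctions alone the shares were 1.1% in pfd246 and 2.81% in Col. Junctions with few reads could not account for it, as the difference with at least 5 reads was -1.72. Reads split between neighbouring gene copies may give such junctions, but lower levels of these genes stay open as the cause of the difference: on those within the RBCS gene cluster of chromosome 5 the share was 0.530% in pfd246 and 1.33% in Col, and RBCS genes such as RBCS1B (4412 against 8605 CPM) were lower in pfd246.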

How the results depend on the processing

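The alternatives fixed before the data were examined and those chosen after are named in the methods. Of 207 values of summary results under an alternative, 139 stayed within 1.5 times (or 1 SD) of the reported value, 68 moved and 0 reversed, and of 313 values with a library left out 228 stayed and 85 moved. For named genes, introns and exon parts 4219 of 4687 values kept their direction and side of the threshold, 464 fell short of it, 4 passed it and 0 reversed. Except where stated the cause was not tested.

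Gene counts by DESeq2, with no filter and with a term for the replicate letter were 715, 723 and 1457 for pfd4 in standard conditions and 1872, 471 and 51 for pfd4 in salt, where all 28 libraries in 1 fit gave 3007 (1038 up). The pfd4 and salt interaction gave 623 and 67 by the first 2 of these. Same-letter correlations were 0.103 to 0.21 for lsm8 and Col in standard conditions and -0.127 to 0.328 elsewhere. Pairing stays open.

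Intron counts with the letter as a term were 4769, 5735 and 8825 for lsm8 in standard conditions, cold and salt, 4 and 2 for pfd4 in standard conditions and salt, 467 for cold in Col, 23 for pfd246 against pfd4 and 6 for the lsm8 and salt interaction. At the second border alone, which has fewer reads, they were 3264, 3856 and 5784 for lsm8, 1 for pfd4 in salt, 36 for pfd246, 401 for cold in Col and 0 for the lsm8 and cold interaction, and with both borders 49 for pfd246 against pfd4. With a coverage of 1 they were 4 for pfd4 in standard conditions, 2 for the lsm8 and 1 for the pfd4 interaction with cold. With a coverage of 30 they were 15 for pfd4 in cold, 2 for pfd4 in salt and 0 for the lsm8 and cold interaction. By limma they were 0, 1 and 1 for pfd4 in standard conditions, cold and salt, 4 for pfd246, 53 for cold in Col, 1 for pfd246 against pfd4, and 0 and 5 for the lsm8 interactions with cold and salt.

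Exon part counts were 12 for lsm8 in standard conditions with a coverage of 30, and 15, 7 and 6 for lsm8 and 6 for pfd4 in cold by limma. With the letter as a term they were 0 for lsm8 in cold, pfd4 in cold and pfd246, and 1 for pfd4 in salt. By limma 0 introns were shared by lsm8 and pfd246 in standard conditions and by lsm8 and pfd4 in cold and salt, and by DESeq2 516 genes by lsm8 and pfd4 in salt (266 for independent lists). Pooled retention rose by 0.573 points in lsm8 in salt at coverage 30. Without junctions that join 2 genes the difference in unannotated junction reads was -0.00883 points in pfd246 and -0.243 in pfd4 in cold. With an estimated correlation 0 lists passed camera in any of the 13 tests.

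With 1 library left out, gene counts ran from 4206 to 6646 for lsm8 in salt, 251 to 664 for pfd4 in standard conditions, 8 to 819 in salt and 9 to 402 for the pfd4 and salt interaction. Where this leaves 1 library in a group, edgeR takes its spread from the other group. Intron counts ran from 3797 to 7613, 4378 to 8719 and 8622 to 11283 for lsm8, 0 to 3, 2 to 16 and 1 to 4 for pfd4 (standard conditions, cold, salt), 20 to 95 for pfd246, 509 to 774 for cold in Col, 3 to 12 for pfd246 against pfd4, 0 to 1 and 5 to 20 for the lsm8 interactions with cold and salt and 0 to 1 for both of pfd4. Exon part counts ran from 0 to 3, 0 to 4 and 44 to 79 for lsm8, 0 to 1, 0 to 5 and 0 to 1 for pfd4 and 0 to 3 for pfd246. The other gene counts stayed within 1.5 times, from 7607 to 9563 for lsm8 in standard conditions, 6831 to 9281 in cold, 5730 to 7112 for pfd4 in cold and 10560 to 12145 for pfd246. At the depth of these libraries the intron test found 29.9% of simulated 4-fold changes in odds in lsm8 and 37.3% in pfd4, and other depths were not simulated.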

Other observations

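The test of intron length was fixed before the data were examined, and the values on single genes across comparisons were chosen after the results were seen.

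AT3G01345 was lower in the mutant in all 7 comparisons with Col (log2 -4.60, -7.01 and -5.41 in lsm8 in standard conditions, cold and salt, -7.53, -8.01 and -8.60 in pfd4, and -5.09 in pfd246), with the calls lost in lsm8 and pfd4 in standard conditions as given above. MRD1, on a locus that overlaps HEI10, was near 0 in pfd4 (0.0872, 0.221 and 0.503 CPM in standard conditions, cold and salt) but stood at 28.9 CPM (SD 1.74) in pfd246 and at 10.2 CPM (SD 3.05) in Col in standard conditions. FLC stood at 0.211 CPM in lsm8, 2.61 in Col, 6.51 in pfd4 and 14.4 in pfd246 in standard conditions. LSM8 itself stood higher in Col in cold (29.9 to 32.9 CPM) than in standard conditions (7.77 to 10.6 CPM).

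In pfd4 in cold the deposited test tables hold 2976 introns, 582 up and 2394 down, against 7 up and 2 down with border reads here, while pooled retention was 1.38% in pfd4 and 1.5% in Col. For lsm8 they hold 5928 up and 923 down in standard conditions, 7591 up and 310 down in cold and 14762 up and 166 down in salt, and for pfd246 1831 up and 642 down.

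Longer introns were predicted to be retained more often in lsm8. They were not: in standard conditions the introns with raised retention had a median length of 89 bases against 101 for the other tested introns, a difference of -12 (permutation p = 5e-04, the smallest that 2000 permutations can give; introns are not independent replicates). The medians were 92.5 and 101 in cold and 93 and 102 in salt, while in pfd246 they were 157 and 100 (permutation p = 0.001). The second prediction, on splice sites that lack G at position 5 of the intron, was not run because no genome was used.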
